A study of Mus musculus with 2 samples.

How the data were processed

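Accessible chromatin was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in 2 mouse libraries of fetal liver cells from embryonic day 14.5. The cells were sorted as negative for lineage markers and positive for c-Kit, the stem cell factor receptor, a gate that holds blood stem and progenitor cells. Each library was made from 150000 cells, per the labels. One library came from Brd9fl/fl cells (control, replicate 1) and the other from Vav1-iCre Brd9fl/fl cells (knockout, replicate 2). How many embryos went into each library is not given in the sources used here. Vav1 regulatory DNA drives the Cre recombinase in blood cells, where it removes the floxed part of Brd9, a bromodomain subunit of the non-canonical BAF chromatin remodelling complex.

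Trimmomatic 0.39, Bowtie2 2.4.4, Picard 2.26.2, deepTools 3.5.1 and MACS2 2.2.7.1 are named with the genome build mm10, per the submitters' processing notes, which give neither their roles nor their settings. Whether reads were shifted for the transposase, how duplicates and multi-mapping reads were treated, and whether a blacklist was used is not given in the sources used here. The files carry no headers, and each deposited list belongs to 1 sample, so peaks were called per sample and not on pooled samples. The deposited values are those of the narrowPeak format. The deposited score is 10 times the −log10 q-value without its decimals, which was tested on every row, and it was not used further. The deposited fold is the ratio of the read pileup at the summit to the local background, each with a pseudocount of 1. The deposited −log10 p-value and −log10 q-value compare the same pileup with the same background, and they are the authors' own values for each peak, used here to rank and filter peaks within a list. The lowest deposited −log10 q was 1.31 in the control list and 1.32 in the knockout list, so both lists held peaks with q below 0.05. Peak names were numbered without gaps in each list, no rows overlapped, and the shortest peak was 376 bp in both.

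The number of reads at each summit was recovered from the deposited values, an approach chosen after the files had been seen. The fold and the −log10 p of a peak form a pair of equations in a whole-number pileup and a background. A whole number that gave the deposited −log10 p to within a relative misfit of 7.3e-06 was found for 100.0% of the peaks in both lists. Tested on simulated peaks with the control and knockout backgrounds, the recovery returned the true number for 100.0% of 1999 and of 1998 peaks. These numbers are called summit reads below. They count the extended reads that cover the summit, not all reads of the peak, and how the authors extended reads is not given in the sources used here. The lowest background, which the caller applies across the genome, was 1.52 reads in the control list, at 4000 peaks, and 0.971 in the knockout list, at 3013 peaks. Their ratio of 0.640 served as the relative depth of the knockout library, on the assumption that reads were extended alike; the spacing of the recovered background values was 0.0188 in both lists. Total read numbers were not analysed here, so absolute depth is unknown. Scaled ratios are knockout over control summit reads divided by 0.640. The background counts mitochondrial reads too. In each list 5 peaks with more than 3000 summit reads, 3 on the mitochondrial genome and 2 on chromosome 17, were left out of scaled ratios.

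Overlaps were computed with bedtools 2.31.1, and everything else with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. A peak counted as overlapped when it shared at least 1 bp with a peak of the other list. Both lists were merged into regions, classed as shared, control-only or knockout-only. Intervals are 95% intervals, exact Clopper-Pearson for shares, exact Poisson for summit reads and exact conditional binomial for ratios. Reads without molecular identifiers are not independent molecules, so all intervals cover counting error only. With 1 library per group there was no replicate check and no p-value was computed; every difference is one between these 2 libraries.

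Genes came from a RefSeq table of assembly GRCm38.p6, which has the coordinates of mm10. The table used here gives the outer ends of each gene but no strand or transcripts. Promoters had been planned as the place around transcription start sites; in their stead a region was called a gene-end region when it lay within 1 kb of either end of a gene, a gene-body region when it overlapped a gene otherwise, and intergenic in all other cases. Some internal promoters therefore count as gene body, and some gene-end regions lie at the 3' end. Distances to loci were likewise taken from the gene rather than from a start site. Planned motif counts needed a genome sequence and were not run.

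The 18 gene lists, with 396 genes, were fixed before the data were examined, as were the rule for named genes and most of the alternative settings; 395 genes were found in the table, and Ahsp was not matched. For a list with at least 5 genes that had a shared gene-end region, the median log2 scaled ratio was set against 10000 random lists of protein-coding genes of the same size, matched in 10 bins of summit reads. This could be done for 14 lists. For loci, the share of control-only minus the share of knockout-only regions within 50 kb of the genes was set against 10000 random lists matched on the number of regions per gene, for 17 lists. Percentiles describe these libraries and are not p-values. In simulations with lists of 20 shared regions from any location and no shift, 2.0% of 200 lists fell outside the 2.5th to 97.5th percentile. With a shift of 0.3 downwards on the log2 scale, 78.5% of 200 lists fell below the 2.5th percentile. The simulations used fewer random lists and regions in place of gene ends, so these rates need not hold for the gene lists.

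Named genes followed a fixed rule. It took Brd9, Vav1 and the sex-linked genes; of each list up to 4 genes per direction with a gene-end peak in 1 list alone and up to 3 with peaks in both, by the authors' −log10 q; the 10 one-list regions per library with the highest −log10 q; and the 5 genes per direction with the largest excess of one-list regions within 50 kb. The 10 shared regions per direction outside chromosome Y whose ratio interval lay farthest from 1 were added after the data had been seen. Some genes that the rule took are not reported here. Alternatives included a −log10 q of at least 5, equal numbers of peaks, a reciprocal overlap of 50%, summits inside peaks, distances of 2.5, 10 and 100 kb and protein-coding genes alone. Autosomes alone, another scaling and the removal of height and location medians were added after the data had been seen.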

Results

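Peak lists of 1 control and 1 Brd9 knockout library were compared to learn which chromatin sites of lineage-negative, c-Kit-positive fetal liver cells were accessible with and without BRD9. The control list held 25330 peaks over 21.5 Mb, with a median width of 794 bp and a median of 37 summit reads. The knockout list held 22348 peaks over 17.6 Mb, with a median width of 731 bp and a median of 28 summit reads. The knockout library had 0.640 times the background depth of the control library. There was no replicate of either genotype, so each difference below is between 2 libraries, and the intervals do not cover variation between embryos.

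The region at one end of Brd9 itself (chromosome 13, 73937144 to 73938413, mm10) was present in both lists, with 217 summit reads in the control and 151 in the knockout. Its scaled ratio of knockout over control was 1.09 (95% interval 0.877 to 1.34). The position of the floxed part is not given in the sources used here, so this region checks neither label. At Vav1, the blood-cell gene whose regulatory DNA drives the Cre, a region inside the gene (chromosome 17, 57290151 to 57291114) had 83 summit reads in the control and 163 in the knockout, a scaled ratio of 3.07 (2.34 to 4.04). The other 3 shared Vav1 regions had ratios from 1.04 to 1.39, each with an interval that included 1. The libraries also differed at sex-linked genes. Gene-end regions of Ddx3y and Uty, both Y-linked, stood in the knockout list alone, with 33 (22.7 to 46.3) and 18 (10.7 to 28.4) summit reads. Kdm5d and Eif2s3y, also Y-linked, had no region in either list. At Xist, the RNA that silences an X chromosome in female cells, the region at 103481417 to 103482361 on chromosome X had 86 summit reads in the control and 33 in the knockout, a scaled ratio of 0.599 (0.389 to 0.905), and a second gene-end region was in the control list alone, with 43 reads. Genotype and these sex-linked differences coincided in the 2 libraries.

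Sites listed in 1 library alone were mostly weak, but some were strong. The highest-ranked control-only region lay at an end of Usp12, a deubiquitinase gene (chromosome 5, 146794897 to 146795391), with 158 summit reads (134 to 185). It was followed by regions inside Caskin2 with 135 reads, 35091 bp from Hunk with 92 reads and 2983 bp from Frat1 with 163 reads. Regions near or in Vwc2l, Klf11, Wipi2 and Coro1c, and a pair of regions with no gene within 50 kb, made up the rest of the first 10, with 79 to 93 reads. Among knockout-only regions, the highest-ranked lay at an end of Dmwd (chromosome 7, 19075810 to 19076260), with 88 summit reads (70.6 to 108). Regions at Ola1 with 43 reads, inside Inpp5d, which encodes the blood-cell phosphatase SHIP1, with 52 reads, and inside Cpt1c with 54 reads came next. Ddx3y, Megf6, Actl6b, Dgat2, Tbkbp1 and Sik1 completed the first 10. Many of these regions were narrow, such as those at Usp12 (495 bp) and Dmwd (451 bp), though that in Coro1c had 1082 bp. Control-only regions with at least 40 reads had a median width of 574 bp, against 861 bp for shared regions of like reads. For knockout-only regions these were 466 and 833 bp. The shortest listed peak had 376 bp, so a narrow site may be missing from 1 list through its width.

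Of the control peaks, 73.1% (72.5 to 73.6; 18516 of 25330) overlapped a knockout peak, and of the knockout peaks, 83.1% (82.6 to 83.6; 18572 of 22348) overlapped a control peak. The share depended on peak rank. Of the 2533 control and 2235 knockout peaks with the lowest −log10 q, 20.1% and 30.1% were overlapped, whereas among as many peaks with the highest −log10 q all 2533 control and all 2235 knockout peaks were. With equal numbers of top peaks, 11174 from each list, the shares were 89.6% and 89.8%. The number of peaks in a list also follows depth, which differed between the libraries.

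**Figure D1:**
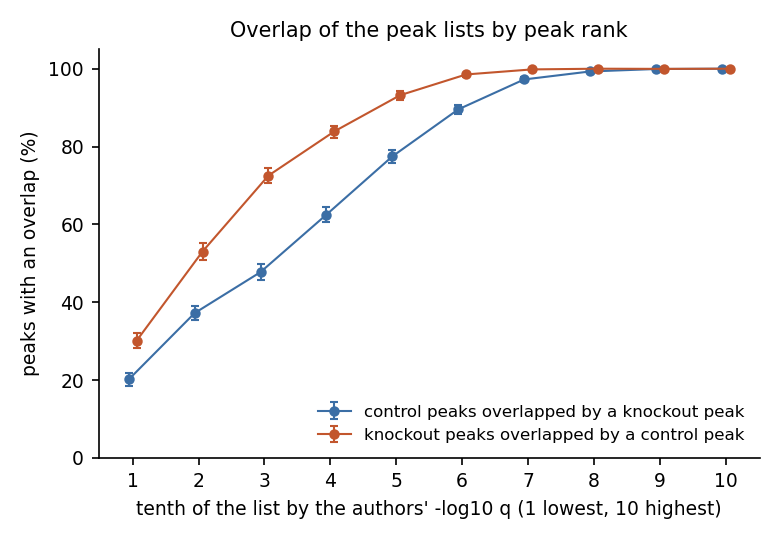
Share of peaks (%, vertical axis) overlapped by a peak of the other list, in 10 groups of equal size by the authors' −log10 q (horizontal axis, 1 lowest to 10 highest); bars are 95% Clopper-Pearson intervals for counting error. The share went from 20.1% of control peaks (blue) and 30.1% of knockout peaks (orange) in the lowest group to all peaks in the highest.

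Merging gave 29076 regions, of which 18486 were shared, 6814 control-only and 3776 knockout-only. Around Ank1, which encodes the ankyrin of the red cell membrane skeleton, 10 control-only regions and 1 knockout-only region lay within 50 kb of the gene, while its shared gene-end region had 32 and 31 reads (scaled ratio 1.51, 0.893 to 2.56). Xpr1 (8 and 0), Gng12 (7 and 0), Maml3 (8 and 1) and Pde11a (7 and 0) were the other genes with the largest excess of control-only over knockout-only regions. In the opposite direction stood Tubgcp2, with 0 control-only and 5 knockout-only regions, and Abl1, Cap1, Ccdc12 and Cebpb, a transcription factor gene of myeloid cells, each with 0 and 4. Shared regions had medians of 61 summit reads in the control and 37 in the knockout, against 14 in control-only and 10 in knockout-only regions. Gene ends held 57.1% (56.4 to 57.8) of the shared regions, 20.97% (20.01 to 21.96) of the control-only and 21.7% (20.4 to 23.0) of the knockout-only regions. Part of this contrast went with summit height. Among regions with 11 to 21 control reads, gene ends held 30.5% of shared and 20.7% of control-only regions, and among those with 8 to 13 knockout reads, 27.8% of shared and 21.5% of knockout-only regions. With equal numbers of peaks, the one-list shares parted, at 35.7% (32.9 to 38.5) for control-only and 49.1% (46.1 to 52.0) for knockout-only regions.

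Among regions in both lists, Kcnn4, the calcium-activated potassium channel gene of red cells, had a clearly lower count in the knockout, with 219 summit reads in the control and 46 in the knockout at a gene end (chromosome 7, 24369825 to 24370466; scaled ratio 0.328, 0.233 to 0.453). Lower counts were also found near Minpp1 (83 and 14 reads) and inside Zc3h4 (247 and 60), Pcx, the pyruvate carboxylase gene (354 and 93), and Tgfbr3 (55 and 9). Gemin8, Ankrd36, Zbtb21 and Tmtc2 were also among the 10 lowest. In the other direction, after Vav1, the region inside Rhpn1 had 15 reads in the control and 41 in the knockout (scaled ratio 4.27, 2.31 to 8.30). At an end of Fes, a myeloid tyrosine kinase gene, there were 33 and 71 reads (3.36, 2.19 to 5.24), and at an end of Lyplal1 35 and 67. Regions inside Zfhx2, inside Cdh23 and Vsir, near Gm39147, 22808 bp from Nrarp, and a pair with no gene within 50 kb were the others of the 10 highest. Over all 18481 shared regions with a ratio, the median log2 scaled ratio was 0.00 (SD 0.46), where counting error alone would give an SD of 0.36. Scaled ratios of at least 2 were found at 442 regions and of 0.5 or less at 367, of which 336 and 323 had an interval that excluded 1. Shared regions had to be called in both lists, and the knockout library was shallower. These counts therefore leave out regions missing from 1 list and do not compare the directions. Among the 3695 shared regions with the most reads the SD was 0.25 against 0.14 from counting, so differences between the libraries exceeded counting error, and how much of this embryos of the same genotype would show was not measured.

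**Figure D2:**
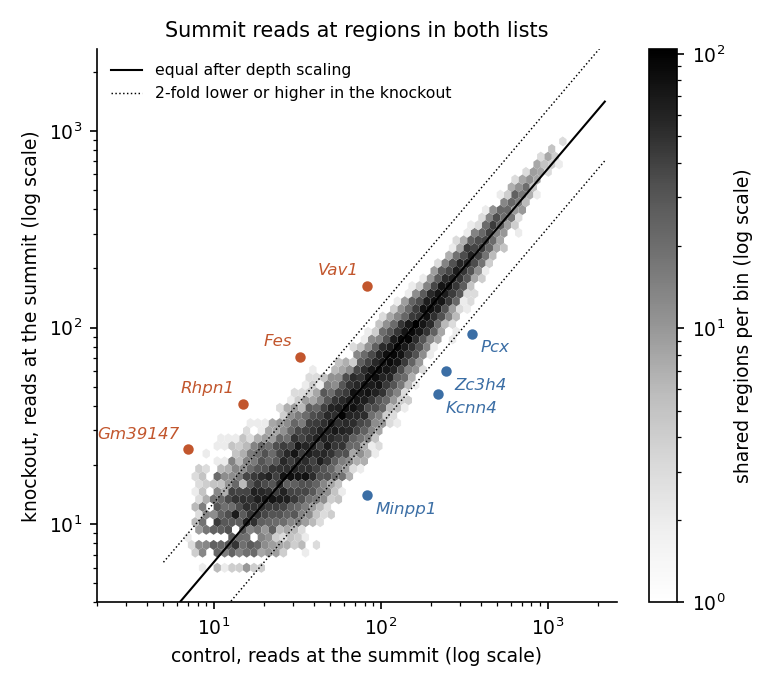
Summit reads of the 18481 shared regions in the control (horizontal axis) and the knockout (vertical axis), both on log scales, with grey bins shaded by the number of regions. The solid line marks equal accessibility after scaling by 0.640 and the dotted lines 2-fold differences; the first 4 regions per direction are named by their nearest gene, among them Vav1 with 83 and 163 reads and Kcnn4 with 219 and 46.

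Genes of the erythroid list had lower summit counts in the knockout at their gene ends. Of 19 erythroid genes with a shared gene-end region, 14 had a scaled ratio below 1, and the median log2 ratio was −0.20, at percentile 0.68 of random lists (central 95% −0.16 to 0.17). Epor, the erythropoietin receptor gene (369 and 197 reads; scaled ratio 0.834, 0.698 to 0.994), Sptb, the erythroid beta-spectrin gene (328 and 164; 0.781, 0.643 to 0.945), Epb41 (379 and 198; 0.816, 0.684 to 0.971) and Car2, a carbonic anhydrase gene (261 and 100; 0.598, 0.470 to 0.756), were among 5 with an interval below 1. In the other direction, Nfe2 (402 and 306; 1.19, 1.02 to 1.38) and Hba-a1 (30 and 35; 1.82, 1.09 to 3.07) had intervals above 1, though the count at Hba-a1 is uncertain, since the gene has a near-identical copy. Hbb-bs, an adult beta-globin gene, and Slc4a1, the band 3 anion exchanger gene, had gene-end peaks in the control list alone, with 50 and 62 reads, as had Slc25a37 with 11; Hbb-bs too has a near-identical copy, Hbb-bt, which had no peak in either list, so its count is likewise uncertain. Aqp1 with 18 reads and Tspan33 with 6 had a gene-end peak in the knockout list alone. The erythroid list was 1 of 14 examined in this way, and no random-list percentile corrects for that number. Away from gene ends, 37 shared regions within 10 kb of erythroid genes had a median of −0.30, with 28 below 0 and 9 above, at percentile 1.18 of random regions. Taken as 1 value per gene, 14 of 16 erythroid genes were below 0 and the median was −0.26, but this stood at percentile 12.4, as random lists of 16 genes spread widely (central 95% −0.35 to 0.10).

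The other 13 lists had medians inside the central 95% of random lists, though the T and NK list left it when gene ends were drawn at 2.5 kb. Genes for BAF complex subunits, a list not limited to the non-canonical complex that holds BRD9, had a median of 0.09 (26 genes, 17 above and 9 below 0, percentile 92.5). Among them Smarce1 (77 and 21 reads; scaled ratio 0.426, 0.250 to 0.697), Arid2 (291 and 107; 0.574, 0.456 to 0.719), Brd7 and Arid1a had intervals below 1, and Smarca4, Smarcd1 and Actl6a (522 and 391; 1.17, 1.02 to 1.34) above 1. Stem and progenitor genes had a median of 0.00 over 22 genes (percentile 46.7), with Tal1 and Lmo2 below and Lyl1 (336 and 283; 1.32, 1.12 to 1.55) and Zfpm1 (1059 and 799; 1.18, 1.07 to 1.29) above. Tal1, a blood stem cell transcription factor gene, had 214 and 61 reads, a scaled ratio of 0.445 (0.329 to 0.594). Granulocyte and monocyte genes had a median of 0.05 over 14 genes (percentile 50.6). Of these, Spi1, which encodes the myeloid factor PU.1 (30 and 38; 1.98, 1.19 to 3.31), and Cebpa (55 and 55; 1.56, 1.05 to 2.31) had intervals above 1, whereas Csf2ra and Id2 had ratios of 1.16 and 1.02 that included 1. Of the p53 and cell-cycle genes (22 genes, median 0.07, percentile 84.4), Trp53 with a ratio of 0.672, Mdm2 with 0.673 and Cdk2 with 0.669 were below 1 and Cdk4 with 1.197 above it. The named genes with an interval that left out 1 but outside the fixed rule, such as Tal1, Car2, Spi1, Smarce1, Trp53, Itgb3, Notch1, Mx2 and Mertk, were chosen after their values were seen. Of 186 listed genes with a ratio, 17 had an interval below 1 and 24 above 1. These intervals cover counting error only, and the share of all gene-end regions with such an interval was not counted. The 3225 gene-end regions among the 3695 shared regions with the most reads had an SD of 0.24 in log2 ratio. Nfe2 (0.25), Zfpm1 (0.24), Actl6a (0.23) and Epor (−0.26) were about that far from 0.

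Megakaryocyte genes had a median of 0.04 (10 genes, percentile 43.4), with Gp9 and Gp1ba at 1.04 and 1.02 and Itgb3 at 2.92 (15 and 28 reads; 1.505 to 5.872); Itga2b, the platelet integrin gene, had a gene-end peak of 36 reads in the knockout list alone. The median was 0.03 for the fetal program (9 genes, percentile 57.5), with Ezh2 at a ratio of 1.07 and Cdk6 at 0.777. It was −0.03 for B-lymphoid genes (6 genes, percentile 47.4), with Tcf3 at 1.32, and 0.20 for T and NK genes (6 genes, percentile 81.8), with Runx3 at 1.68 and Notch1 at 1.84. At 2.5 kb the T and NK median was 0.54 over 8 genes, at percentile 99.2 (central 95% −0.31 to 0.46). Interferon-response genes had −0.11 (11 genes, percentile 22.9), with Stat2 at 0.734. Mx2, which the gene table classes as a pseudogene and which was left out of this median, had a ratio of 3.32 (8 and 17 reads; 1.36 to 8.88). The median was 0.10 for genome-architecture genes such as Smc3 (10 genes, percentile 80.0) and 0.06 for housekeeping genes such as Polr2a (18 genes, percentile 72.5). Of markers of other liver cells, macrophage genes had 0.02 (6 genes, percentile 39.6), with Axl at 1.07 and Mertk at 2.73, and hepatocyte genes 0.26 (5 genes, percentile 80.2), with Apoa2 at 1.21 and Foxa3 at 1.197. Alb, Afp and Ttr, abundant hepatocyte genes, had no gene-end peak in either list. Too few genes were left for a median in the mast cell and basophil list, where Mitf had a ratio of 1.17, the endothelial list, where Flt4 had 0.766, and the stromal list, where Col1a1 had 1.02 and Ncam1 2.23.

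**Figure D3:**
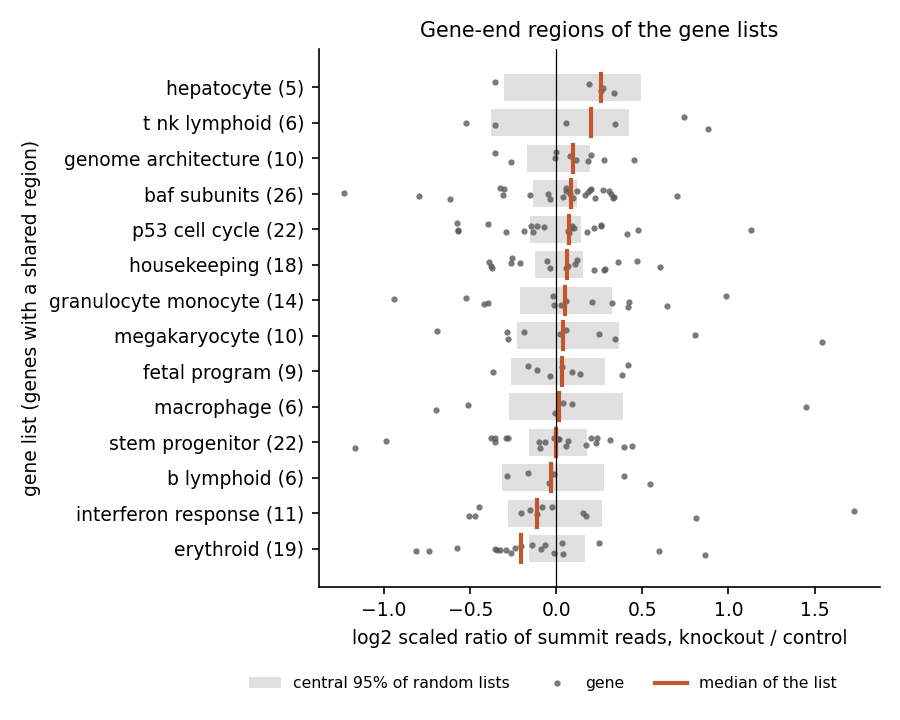
Log2 scaled ratio of summit reads, knockout over control (horizontal axis), at gene ends for the 14 lists with at least 5 genes, the number of genes in parentheses. Points are genes, orange bars list medians, and grey boxes the central 95% of 10000 random lists; the erythroid median of −0.20 lies outside its box and the other 13 medians lie inside theirs.

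Most listed genes did not differ in whether a gene-end peak was present. Of 395 genes, 187 had one in both lists, 14 in the control list alone, 12 in the knockout list alone and 182 in neither. Control-only genes outside the erythroid list included the B-lymphoid factors Ebf1 (33 reads) and Irf4 (18) with Igll1 (21), the stem cell genes Hoxa5 (24) and Tek (12), and Tlr2, Plek, Cd4, Eng, Lhx2 and Col1a2 with 9 to 20 reads. Knockout-only genes included the stem cell factors Hoxa9 (19 reads) and Hlf (15), and Tubb1, S100a8, Eomes, Stab1 and Ddx58 with 7 to 12 reads. At such counts a site near the detection limit of one library can be missed in the other, so absence of a peak does not show that a site was closed. B-lymphoid genes were 3 to 0 towards the control, and no list had more than 3 genes in one direction.

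Around the stem and progenitor genes, 73 of 229 regions within 50 kb were control-only and 35 knockout-only, a difference of 16.6 percentage points at percentile 97.9 of random lists. This exceeded the difference of 10.4 points over all regions, but it stood at percentile 82.4 when loci were limited to 10 kb (14.8 points). It was 18.2 points within 100 kb (percentile 99.9) and 22.2 points among peaks with a −log10 q of at least 5 (percentile 99.7). Of the 229 regions, 31.9% were control-only and 15.3% knockout-only. Both shares were above those over all regions, 6814 and 3776 of 29076. Random lists were matched on the number of regions, not on the share of one-list regions. The stem and progenitor list was 1 of 17 examined in this way, and no percentile corrects for that number. Around hepatocyte genes the difference had the opposite sign, −4.62 points (9 control-only and 12 knockout-only of 65 regions; percentile 1.5), and it was 6.00 points among peaks with a −log10 q of at least 5. The other 15 lists lay between percentiles 2.82, for stromal genes (−9.38 points of 32 regions, and 4.35 points among peaks with a −log10 q of at least 5), and 90.8, for mast cell and basophil genes (6 control-only and 1 knockout-only of 20 regions); the erythroid list stood at 59.5 (9.96 points of 231 regions). Some of these moved with the setting. Mast cell and basophil loci had 42.9 points within 10 kb, from 7 regions (percentile 97.8), and among peaks with a −log10 q of at least 5 they had 6.25 points (percentile 37.9), T and NK loci had 1.04 points (percentile 1.84, against 37.0 with all peaks) and erythroid loci had 16.4 points (percentile 87.5).

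Autosomes held like shares of both lists. Chromosome 11 had the largest share, 8.13% of control and 8.04% of knockout peaks, and chromosome X had 2.38% and 2.32%. On chromosome Y there were 3 control and 5 knockout peaks. Besides Ddx3y and Uty, 3 regions between 90738240 and 90812998 were in both lists, with scaled ratios of 2.33, 1.43 and 4.31. The median log2 scaled ratio per autosome lay between −0.05 and 0.06, and it was −0.04 on chromosome X.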

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

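The peaks with more than 3000 summit reads were not used in the comparisons above, and their scaled ratios stood above those of most regions. On the mitochondrial genome the 3 peaks had 40836, 24733 and 39551 summit reads in the control and 35708, 21467 and 34788 in the knockout, scaled ratios of 1.37 (1.35 to 1.39), 1.36 (1.33 to 1.38) and 1.37 (1.35 to 1.39). On chromosome 17, the 2 peaks at the ribosomal RNA gene Rn18s-rs5 had 14661 and 9572 summit reads in the control and 12391 and 7840 in the knockout, scaled ratios of 1.32 (1.29 to 1.35) and 1.28 (1.24 to 1.32). Both places exist in many copies per cell.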

How the results depend on the processing

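No paired analysis was possible because the control and the knockout share no replicate number and each group is 1 library; for the same reason no library could be left out in turn. Motif alternatives were not run, since they need a genome sequence. The share of control peaks overlapped was 76.2% among peaks with a −log10 q of at least 5, 89.6% with equal numbers of peaks, 67.4% with a reciprocal overlap of 50%, 70.9% with the summit inside a peak and 80.8% with the threshold applied to the control list alone. The share of knockout peaks overlapped was 89.6%, 89.8%, 76.4%, 81.4% and 91.9% in the same order, the last with the threshold applied to the knockout list alone. The gene-end share of shared, control-only and knockout-only regions was 60.3%, 22.8% and 25.5% at a −log10 q of at least 5, 74.9%, 35.7% and 49.1% with equal numbers, 64.1%, 31.9% and 33.9% within 2.5 kb, and 50.2%, 14.4% and 14.6% for protein-coding genes. With the −log10 q limit, a one-list region could still hold a lower-ranked peak of the other list, and with equal numbers most did. Wider or narrower definitions of overlap and gene end move these shares by construction, and the cause of the other shifts was not tested. At loci of hepatocyte genes the difference turned from −4.62 to 6.00 points at a −log10 q of at least 5, and was −16.7 within 10 kb and 0.00 within 100 kb; at stromal loci it went from −9.38 to 4.35, 0.00 and 1.70 points under these settings. The cause was not tested. Chosen after seeing the data, autosomes alone gave overlaps of 73.0% and 83.0%, and the erythroid median stayed between −0.21 and −0.17, at percentiles from 0.56 to 1.24, under 5 alternatives. Autosomes alone kept the same 19 genes, and the other scaling moves the list and the random lists alike. Removal of height and location medians could change little, as lists were matched on summit reads at gene ends. The 2.5 kb distance and the −log10 q limit gave −0.17 and −0.19, at percentiles 1.24 and 0.92. The T and NK median went from 0.20 to 0.54, at percentile 99.2, at 2.5 kb. Scaling by the sum of summit reads raised every log2 ratio by 0.04 and turned the sign of the stem and B-lymphoid medians. The sums cover 21.5 Mb with a mean of 85.9 reads and 17.6 Mb with a mean of 60.9 reads. Median summits held 37 control and 28 knockout reads, so many sites of both lists lie where counting error is wide.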

Other observations

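Histone genes had lower summit counts in the knockout at their gene ends, a group examined only after the data had been seen. Among 68 histone genes with a shared gene-end region, which fell on 45 distinct regions, 38 regions had a scaled ratio below 1 and 7 above 1. The median log2 scaled ratio of these regions was −0.16, at percentile 0.00 of random gene-end regions of like height (central 95% −0.01 to 0.14), and the sign did not turn with the other scaling, which adds 0.04. The histone genes of chromosome 13 held 30 of the regions, with a median of −0.19 and 27 below 1, and those of chromosome 3 held 7, with a median of −0.15 and 6 below 1. Examples were H2ac10 (chromosome 13, 23534599 to 23535824) with 765 control and 304 knockout reads and H4c18 with 250 and 100, while H4c1 had 890 and 571 reads, a log2 ratio of 0.00. Histone genes are near-identical copies in clusters, so reads shared between copies are uncertain and neighbouring regions are not independent. Of the 14 gene families examined by symbol, histone genes alone lay outside the central 95% of random lists. Cytosolic ribosomal protein genes had a median of −0.01 over 84 genes, mitochondrial ribosomal protein genes 0.05 over 74, proteasome genes −0.08 over 37 and protocadherin genes 0.30 over 24, with 21 above 0 (percentile 87.6).

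The log2 scaled ratio also went with location. Among shared regions with a height of 43.5 to 80.6 reads, the geometric mean of the control and the scaled knockout summit reads, the median was −0.19 for 1206 gene-body regions, −0.13 for 385 intergenic regions and −0.04 for 2100 gene-end regions. Among those with a height of at most 24.3 reads it was 0.16, 0.18 and 0.20. Regions this low count as shared only when called in the shallower knockout list too. This selection can raise the ratio by an amount not measured here, so no trend with height is read from these values. The gap varied: with a height of at least 164 reads, the medians were −0.05 for gene-body, −0.08 for intergenic and 0.04 for gene-end regions. Over all shared regions they were −0.06, −0.0004 and 0.01.

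Of the tests below, the thinning of control reads and the test of erythroid regions away from gene ends were set before their results were seen, and the others were chosen afterwards. By the rule set in advance thinning alone would have supported depth; the comparison of unpaired peaks was added after that result was seen, as was the matching on reads in the test of width. Genotype was not separable from the sex-linked differences, the library or the embryos used, whose number per library is not given in the sources used here, so a role of BRD9 stays open for each pattern.

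The excess of control-only over knockout-only regions (6814 against 3776) may come in part from read depth. When control summit reads were thinned to 64.0% in 20 draws, a mean of 23958 control peaks still met the lowest −log10 p of the knockout list, against 22343 knockout peaks, within the 10% set in advance. But thinning removed only 1367 of the 2982 peaks by which the lists differed. Of the peaks that passed, 5751 had no knockout peak, against 4079 knockout peaks with no passing thinned control peak. Overlapped peaks pair nearly 1 to 1, so this gap largely restates the difference in list size and is not separate evidence. Thinning took no account of the required peak length. Its share of 64.0% also counts mitochondrial reads, whose peaks had scaled ratios of 1.36 to 1.37, so the relative depth of nuclear reads may be lower. Whether depth accounts for the rest therefore stays open. For strong control-only regions, with at least 40 reads, a candidate explanation is the shortest length of a listed peak, since 54.8% (49.7 to 59.7) of 400 such regions, and 72.4% (52.8 to 87.3) of 29 such knockout-only regions, were narrower than the 10th percentile of shared regions within 10% of their reads.

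Removing the medians of summit height and location left the erythroid list median at −0.21, still below the 2.5th percentile. This removal could change little, since all values came from gene ends and random lists were already matched on summit reads. The percentile of 0.68 before removal had thus already allowed for both, within the width of the 10 bins. Chance among 14 lists stays open. The 37 shared regions within 10 kb of erythroid genes but not at gene ends had a median of −0.30, at percentile 1.18 of random regions. In the same test megakaryocyte genes stood at percentile 99.1 (0.24), interferon-response genes at 98.5 (0.31) and BAF subunit genes at 2.60 (−0.28). Regions of a gene are not independent, and with 1 value for each of 16 erythroid genes the median was −0.26, with 14 genes below 0, at percentile 12.4, inside the central 95% (−0.35 to 0.10). More cells of other liver types in the knockout library were not decided by the hepatocyte median of 0.26, from 5 genes at percentile 80.2, although the c-Kit-positive gate would remove hepatocytes and 19 of their 24 listed genes, Alb and Afp included, had no gene-end peak in either list; a different share of erythroid progenitors was not tested.

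The Vav1 region with a ratio of 3.07 (log2 1.62) was the highest of 1614 regions of like read number, the next being at 0.92. Only high ratios were counted in this test. In the other direction Kcnn4, a region of like read number, was about as far from 0, at −1.61. The region was also taken as the highest of the shared Vav1 regions, so spread between the libraries was not excluded. Extra copies of part of Vav1 carried by the Cre transgene were neither supported nor excluded, since 0 of the 3 other shared Vav1 regions had a lower limit above 1 and whether the transgene holds any of these regions is not given in the sources used here. For the same reason the ratio of 3.07 (2.34 to 4.04) does not decide whether genotype labels were exchanged. A true difference in accessibility stays open too.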
